A study of Homo sapiens with 2 samples.

How the data were processed

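Chromatin immunoprecipitation followed by sequencing was carried out in SKOV-3 cells, an established human ovarian carcinoma line. Per the labels' protocols, the cells were transfected with a plasmid expressing a Flag-tagged form of the zinc finger transcription factor EVI1, named Evi1Δ324, and harvested 3 days later. Crosslinking lasted 10 minutes with formaldehyde at 1%, the chromatin was sheared to 200 to 500 bp, and the Flag M2 antibody was used for precipitation. The labels' protocols give 10 ng of precipitated DNA, 15 PCR cycles and selection of fragments of 200 to 300 bp. The series has 1 ChIP library and 1 input library, without replicates. The ChIP peak list was analysed; no file of the input sample was analysed here.

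The deposited list gives a position and 2 values for each peak and has no header. The build is hg18, per the submitters' processing notes, and sequence names in the list occur in that build. The aligner, the peak caller and its thresholds are not given in the sources used here. The first deposited value was read as a fold, a ratio of the peak's height to a background. Among the 4130 peaks whose second value was 5, the first value of 1574 (38.1%) was a whole multiple of a single step of 4.90, within a tolerance of 0.012. These lay at 3 steps in 794 peaks, 4 steps in 667 and 5 steps in 113. Across the list 2099 peaks lay on such a multiple, and in 0 of them did the multiple exceed the second value. The second deposited value was therefore read as the count of tags in the peak, unscaled. Both readings come from the values, and how the background was set is not known. The fold is the authors' own value and was used to describe, rank and filter peaks within this list. A peak on a whole multiple of the step was taken to have the lowest background. A background index was computed as tags per kb divided by fold. Total sequencing depth is not known from the list.

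Peak midpoints were placed on hg18 Giemsa bands and placed contigs taken from the R packages circlize 0.4.16, IRanges 2.36.0 and GenomeInfoDb 1.38.1, under R 4.3.3. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Positions are printed from 1. For chromosomes 1 to 22 and X, the count of peaks was compared with the share of placed contig length by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over 23 chromosomes and exact Clopper-Pearson 95% intervals. Giemsa classes were compared with their placed length, with two-sided p-values from 10000 circular shifts of all midpoints along the joined contigs, which keep the spacing of peaks, and adjustment over the 5 classes. The share of peaks with the next midpoint within 10 kb was compared with 1000 random placements that kept the number of peaks per chromosome. Bands have exact Poisson 95% intervals. The threshold was an adjusted p of 0.05. Peaks are not replicates: all p-values and intervals describe counting within this 1 peak list and say nothing of the spread between cultures.

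The tests were checked on simulated lists of 6873 peaks, 20 per setting, with 400 circular shifts each. With uniform placement, the chromosome test called a mean of 0.05 chromosomes, a Giemsa class was called in 1 of 20 lists and clustering in 2 of 20. A density raised 1.5-fold in Giemsa-negative bands was called in 20 of 20 lists, at a mean ratio of 1.22. With 3 chromosomes raised 1.5-fold, a mean of 2.9 were called, and seeded pairs of peaks were called in 20 of 20 lists. The uniform lists placed each peak independently, whereas the observed peaks lie in groups. This check thus does not cover the binomial and Poisson intervals for grouped peaks, which can be too narrow.

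The items to be named were fixed before the data were examined: the 10 peaks with the highest fold, the 10 densest windows of 100 kb, and the 10 bands with the highest and the 5 with the lowest observed/expected ratio among bands with at least 5 expected peaks. The rule set no order for ties. Tied peaks and windows were ordered by tags and tied bands by expected count, an order chosen after the values were seen. The bands 17q12, 8q24.21 and 3q26.2 were also chosen beforehand. Alternatives fixed beforehand were the peaks with a fold above the median (14.7) or above the 90th percentile (20.8), merging of peaks at most 1 kb or 10 kb apart, full lengths with gaps, leaving out pericentromeric and heterochromatic bands with 1 Mb around each centromere, an expectation within chromosomes, covered bases, distances of 2 and 50 kb, and leaving out the highest 1% of folds. Minimums of 8 and 20 tags, leaving out the outer 5 Mb of each chromosome end, leaving out chromosome 7 for the Giemsa classes and leaving out pericentromeric bands for clustering were added after seeing the data. Gene features, gene lists and motifs had been planned but were not analysed here, since they need an annotation or sequence of hg18. Gene names in the text were matched to the RefSeq annotation of GRCh38.p14 by symbol alone, without its coordinates.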

Results

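To map binding of Flag-tagged Evi1Δ324, chromatin of SKOV-3 ovarian carcinoma cells was precipitated with an antibody against the tag. EVI1, the product of MECOM, is a zinc finger transcription factor. The list held 6943 peaks, none overlapping another, with a median width of 126 bp (range 49 to 7212) and a summed width of 1017 kb. Of these, 6873 lay on chromosomes 1 to 22 and X, where they covered 0.0352% of the 2832 Mb of placed sequence. There were no replicates, and intervals below cover counting error only.

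Most peaks rested on few tags. Exactly 5 tags, the minimum in the list, supported 4130 peaks (59.5%, exact 95% interval 58.3 to 60.6), and 5962 (85.9%) had at most 7. Only 48 peaks (0.691%) had 100 tags or more. The 10 peaks with the most tags held 25.2% of the 76115 tags in the list, 9 of them being pericentromeric and the other in 3q26.2. The median fold was 14.7 (range 1.48 to 74.4). Across peaks, which are not independent replicates, Spearman's rho was -0.152 between fold and width, 0.656 between tags and width, and -0.0369 between fold and tags.

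The first comparison asked whether peaks followed the length of the chromosomes. Chromosome 19 had the highest density, with 266 peaks against 135 expected from placed length (ratio 1.97, 95% interval 1.74 to 2.21, exact binomial test, adjusted p = 9.66e-23). Chromosome 22 followed at 1.83, then chromosomes 17 and 16 at 1.58 and 1.56. Chromosome 7 had the lowest, with 88 peaks against 376 expected (ratio 0.234, interval 0.188 to 0.288, exact test, adjusted p = 1.51e-72). Chromosomes 14, 3, 5 and X were also below expectation, at 0.625, 0.698, 0.712 and 0.840. In the exact binomial test, 9 chromosomes had more peaks than expected, 5 had fewer and 9 passed in neither direction. Chromosomes 20, 21, 11, 6 and 12 completed the higher group, at 1.16 to 1.40. Copy number of the cell line was not corrected. With at least 20 tags required, chromosome 7 no longer passed (0.750, exact test, adjusted p = 0.638) and chromosome 6 fell to 0.347 (adjusted p = 0.0483). Given the minimum of 5 tags, the only bands of chromosome 7 with tags enough for such a peak lay at or next to the centromere. These were the centromeric band 7p11.1 (5 peaks, 94 tags) and 7q11.21 (14 peaks, 295 tags).

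**Figure D1:**
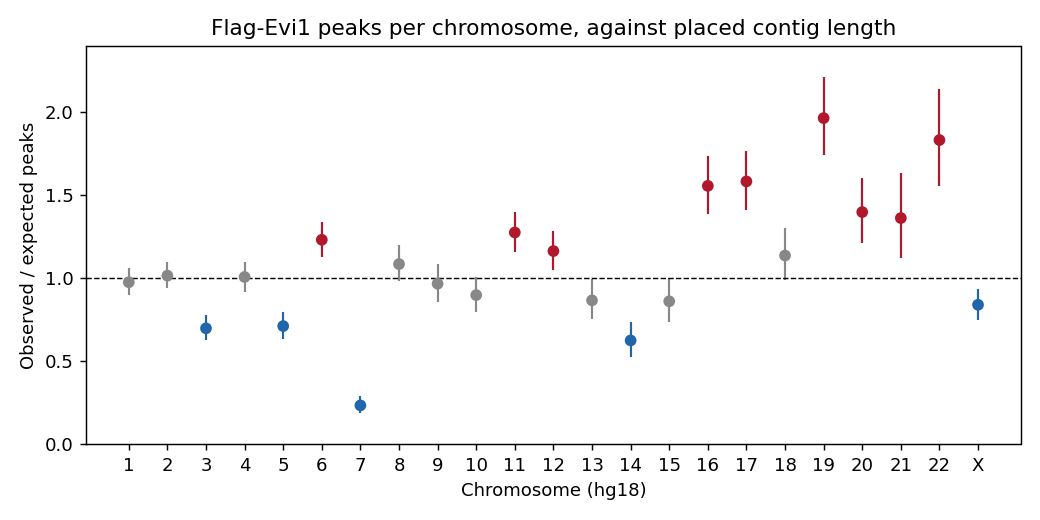
Observed over expected number of peaks for chromosomes 1 to 22 and X, with exact 95% intervals as bars; the dashed line marks a ratio of 1. Red points passed the adjusted threshold above expectation, blue points below it and grey points did not pass; chromosome 7 lies lowest at 0.234 and chromosome 19 highest at 1.97.

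The second comparison asked whether peaks were denser in Giemsa-negative bands, which are gene-rich and replicate early, than in the darkly staining gene-poor bands. The series has no Flag precipitation from cells without the construct, and GC content was not examined here. The ratios are thus not a measured preference of the protein. Giemsa-negative bands held 3557 peaks against 3082 expected, a ratio of 1.15 (adjusted p = 0.00083, a permutation p from circular shifts). The 2 darkest classes held fewer, gpos75 at 0.739 and gpos100 at 0.720 (permutation, adjusted p = 0.00075 for each). The lighter classes did not pass, gpos25 at 1.12 (permutation, adjusted p = 0.18) and gpos50 at 0.949 (adjusted p = 0.38). Centromeric bands held 141 peaks against 65.0 expected (ratio 2.17) and were not part of the adjusted test. With at least 8 tags required, gpos25 rose to 1.59 and gpos50 fell to 0.605, both with an adjusted p of 0.028. With at least 20, neither passed, at 1.75 (adjusted p = 0.13) and 0.393 (adjusted p = 0.11), both by permutation.

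**Figure D2:**
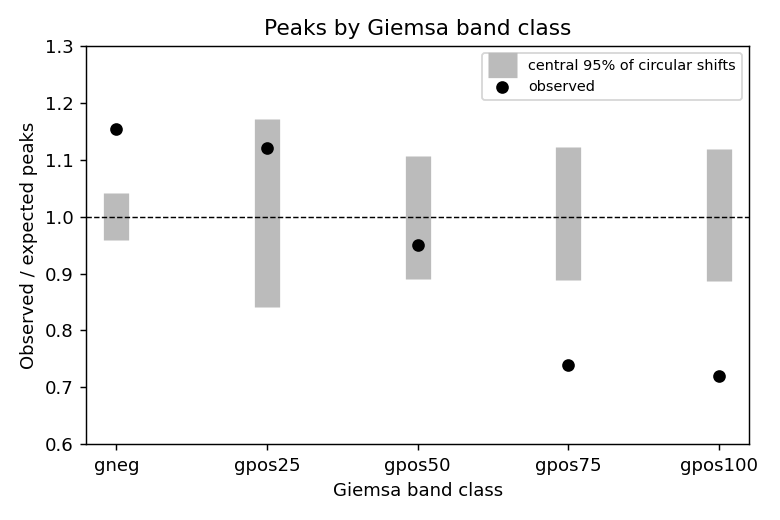
Observed over expected peaks (black points) for 5 Giemsa classes, from unstained (gneg) to darkest (gpos100), with the central 95% of 10000 circular shifts in grey. Points for gneg, gpos75 and gpos100 lie outside the grey range; the vertical axis does not start at 0.

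Among the 613 bands with at least 5 expected peaks, the densest was 19p13.3, with 76 peaks against 16.7 expected (ratio 4.55, exact Poisson 95% interval 3.58 to 5.69). Next were 11q13.1 at 4.33, 12q24.33 at 4.07, 17q21.31 at 3.81 and 12q24.31 at 3.22. The list went on with 16q13 at 3.18, 1p36.32 at 2.99, 6p22.1, which holds a cluster of histone genes, at 2.93, 16p13.3 at 2.88 and 20q11.21 at 2.77. Of these 10 bands, 8 were Giemsa-negative. At the other end, 18 of the 613 bands had none. The 5 with the largest expectation were 7q21.3 (12.9 expected), 12p12.3 (12.4), 3p24.1 and 3p22.3 (10.7 each) and 7p21.1 (10.4). The upper limit of the ratio was 0.287 for 7q21.3 and 0.354 for 7p21.1. These bands were picked as extremes, so their intervals are not corrected for the choice. With peaks at most 1 kb apart merged, 19p13.3 was at 2.99, below 11q13.1 and 17q21.31 (3.73 each), 12q24.33 (3.22) and 6p22.1 (3.12), and with 10 kb it was at 2.71.

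Peaks also lay in groups. The next peak was within 10 kb for 658 of 6873 peaks (9.57%, exact 95% interval 8.89 to 10.3), against a mean of 2.65% in random placements and a maximum of 3.22% (p = 0.001, the smallest that 1000 placements can give). Within 2 kb the share was 6.75% against 0.536%, or 12.6 times the random share. Within 50 kb it was 20.3% against 12.5%, or 1.63 times. The densest window of 100 kb, in 19p13.3 (chromosome 19, 300001 to 400000), held 18 peaks with a median fold of 23.9, where 0.243 was expected. The window of chromosome 2 from 87400001 to 87500000 in 2p11.2 held 13, that of chromosome 11 from 65000001 to 65100000 in 11q13.1 held 11, and that of chromosome 12 from 123500001 to 123600000 in 12q24.31 held 10. The other 6 held 7 peaks each, in 4p11, 8q24.3, 2p11.1, 12q24.31, 16p13.3 and 17p11.2. Merging peaks at most 1 kb apart lowered the excess to 3.69% against 2.44%.

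The 10 peaks with the highest fold all lay in Giemsa-negative bands, and 5 of them were within 5 Mb of a chromosome end. The highest, at 17q25.3 (chromosome 17, 76518246 to 76519028), had a fold of 74.4 and 257 tags. It was followed by 11p15.5 (chromosome 11, 2104691 to 2105264) with a fold of 73.5 and 44 tags, and 1q44 (chromosome 1, 245015735 to 245015945) with 72.7 and 25 tags. Several places were taken by 4q35.1, at chromosome 4 from 186124230 to 186125120 (fold 63.7), from 186123377 to 186124207 (53.9) and from 185008894 to 185010590 (53.3). The others had folds of 53.3 to 53.9, at 11p15.5 (chromosome 11, 1371572 to 1372935), 16q13 (chromosome 16, 56296887 to 56297118), 16q24.3 (chromosome 16, 87262086 to 87262308) and 11q13.1 (chromosome 11, 65945731 to 65945998).

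The peaks with the most tags had low folds, although the median fold was higher with more tags below that range. No multiple of the step exceeded the tags, so few tags limit the fold and this rise may be partly built in. The median fold was 14.7 at 5 tags, 14.9 at 6 to 7, 16.2 at 8 to 19 and 20.5 at 20 to 99, and 4.03 at 100 or more. Of 43 peaks with 100 tags or more on chromosomes 1 to 22 and X, 38 had a fold under 10. Of these 38, 24 were pericentromeric or heterochromatic, 7 were in 3q26.2 and 7 elsewhere. The peak with the most tags, at 6p11.1 (chromosome 6, 58884056 to 58888135), had 5144 tags and a fold of 1.66.

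**Figure D3:**
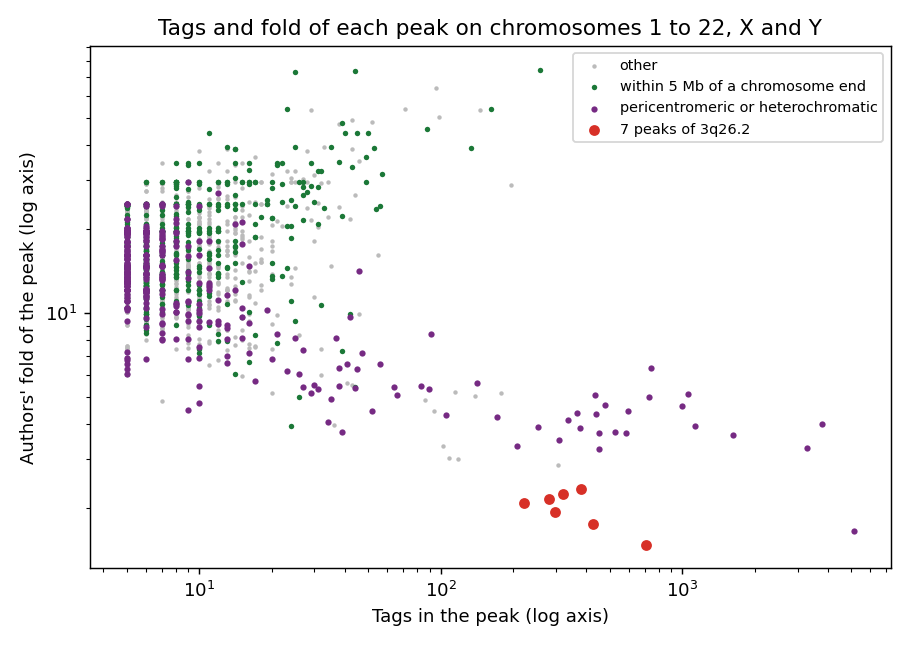
Tags in each peak (horizontal, log axis) against the authors' fold (vertical, log axis), with 1 point per peak coloured by location. The 7 peaks of 3q26.2 (red) combine 221 to 707 tags with folds of 1.48 to 2.34, next to the pericentromeric peaks (purple), while peaks near chromosome ends (green) reach a fold of 74.4.

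The last comparison concerned 3 bands where amplified or transfected DNA can give peaks. The band 3q26.2, which holds MECOM, the gene of the transfected protein, had 17 peaks against 8.01 expected (ratio 2.12, exact Poisson 95% interval 1.24 to 3.40). The band 17q12, which holds the receptor tyrosine kinase gene ERBB2, amplified in this line, had 34 against 15.5 (ratio 2.19, interval 1.52 to 3.06). Chromosome 17 as a whole was at 1.58, inside that interval. The band 8q24.21, which holds the transcription factor gene MYC, had 13 against 10.2 (ratio 1.28, interval 0.679 to 2.18), a difference not detectable at this number of peaks. In 3q26.2, 7 peaks with 100 tags or more lay within 43.2 kb (chromosome 3, 170285368 to 170328594). They had 221 to 707 tags each and a median fold of 2.09, and all 7 were among the lowest 1% of folds. The other 10 peaks of the band had 5 to 17 tags and a median fold of 14.3. Only 8 peaks in the list had a fold under 2.5, and 7 of them were these. With peaks at most 10 kb apart merged, the ratio of 3q26.2 was 1.66 and its interval included 1; among peaks with a fold above the median, 3q26.2 was at 1.25 and 17q12 at 1.29, and both intervals included 1. Above the 90th percentile of fold 3q26.2 had 0 peaks, and 8q24.21 fell below 1, to 0.394 above the median fold and 0.714 with at least 8 tags. Few peaks were expected per band in these subsets, so such values show no reversal. With at least 8 and 20 tags required, the ratios rose to 8.18 and 30.8 for 3q26.2 and to 5.16 and 6.81 for 17q12. All peaks of 3q26.2 with 20 tags or more were the 7 of low fold. Those of 17q12 also had low folds, of 3.34, 5.99 and 5.18 against a list median of 14.7. Their background indices were 109, 13.5 and 11.3, against a list median of 2.81.

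**Figure D4:**
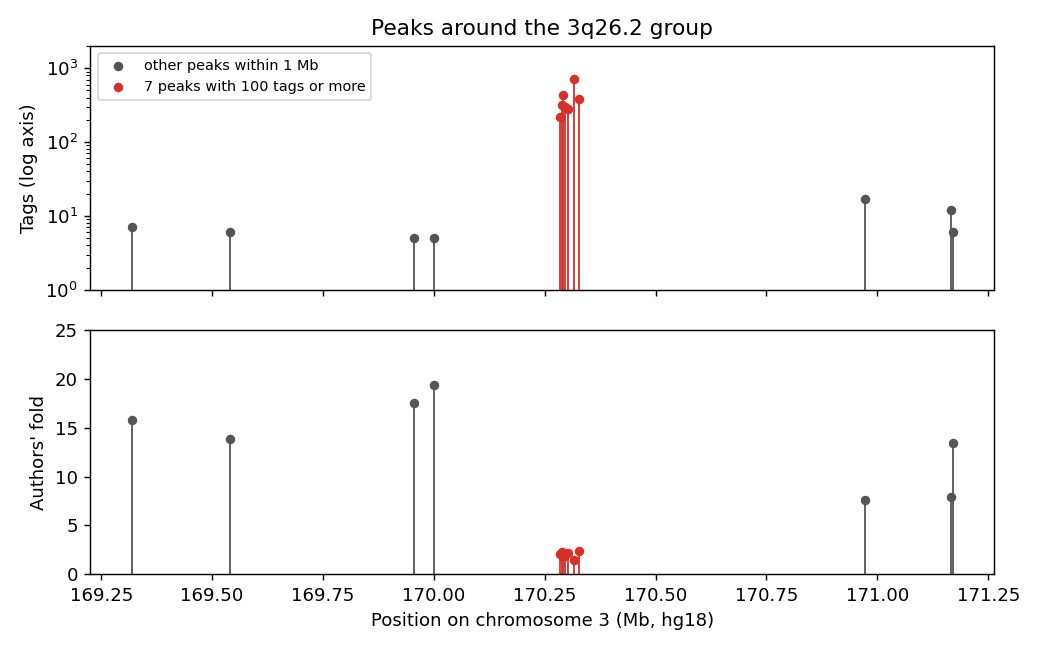
Tags (upper panel, log axis) and authors' fold (lower panel) of peaks on chromosome 3 within 1 Mb of the group in 3q26.2, by position in Mb. The 7 peaks of the group (red) have 221 to 707 tags and folds up to 2.34, and the 7 other peaks (grey) have at most 17 tags and a median fold of 13.8.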

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

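Peaks outside chromosomes 1 to 22 and X entered no comparison with placed length or random placement. They were included in the summary of the list, in Spearman's rho across peaks and in the median fold by number of tags. There were 27 peaks at reference positions of chromosome Y, holding 1358 tags. Of these peaks, 13 were in Yp11.31 and Yp11.32 together and 14 were pericentromeric or heterochromatic, 7 of them in the heterochromatic band Yq12. Since SKOV-3 is an ovarian carcinoma line, they were not read as sites on a Y chromosome. A single peak in Yq11.1 held 999 tags with a fold of 4.63. A further 43 peaks with 1388 tags were on 11 unplaced or alternative sequences, led by the unplaced sequence of chromosome 17 with 15 peaks. Neither count has a control to be set against here.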

How the results depend on the processing

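Minimums of 8 and 20 tags were chosen after seeing the data, as were the other added alternatives named under processing. Of 234 comparisons of a result with an alternative, 190 kept direction and side of the threshold, or for counts stayed within 1.5 times. The ratio of Giemsa-negative bands stayed at 1.11 to 1.45 over 12 alternatives, gpos75 at 0.0362 to 0.789, and gpos100 at 0.0873 to 0.773; chromosome 19 was at 1.68 to 5.11 over 9. By construction, peaks with a fold above the median numbered 3452 and those above the 90th percentile 686, and merging within 10 kb gave 0 for the clustering ratio. Above the 90th percentile, 5 chromosomes exceeded expectation. Over full lengths with gaps, 8 had fewer peaks and gpos50 was at 1.01. Of the 9 chromosomes called higher in the main test, 8 were kept over full lengths and 4 with 20 tags or more. Of the 5 called lower, 4 were kept with merging within 1 kb or 10 kb and 3 with 20 tags or more. With 8 tags or more, gpos25 was 1.59 and gpos50 0.605, calls that were absent with 20 or more (1.75 and 0.393); with 20 or more, chromosome 7 was 0.750. Without the highest 1% of folds, rho between fold and width was -0.180. The ratio of 3q26.2 was 1.25 above the median fold, 0 above the 90th percentile and 1.66 with 10 kb merging; that of 17q12 was 1.29 and 2.60 above the median and the 90th percentile. With 8 and 20 tags or more both moved upward, 3q26.2 to 8.18 and 30.8 and 17q12 to 5.16 and 6.81. In both bands the peaks of 20 tags or more had low folds. Merging within 1 kb and 10 kb lowered 19p13.3 to 2.99 and 2.71. The ratio of 8q24.21 was 0.394 above the median fold, 0.714 with 8 tags, and 0 above the 90th percentile and with 20 tags. Of the named bands, 20q11.21 was 0 above the 90th percentile, and 6p22.1, 17q21.31 and 20q11.21 were 0 with 20 tags. Except where construction is named, the cause was not tested. The few tags per peak limit every such subset. On chromosomes 1 to 22 and X, 682 peaks were left above the 90th percentile, 944 with 8 tags and 195 with 20. In the full list of 6873, 20q11.21, 6p22.1 and 17q21.31 had only 5.42, 9.22 and 9.71 expected. Band ratios in these subsets thus rest on very few expected peaks, and a ratio of 0 there shows no reversal. Gene features, gene lists and motifs, with their alternatives, were not run.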

Other observations

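The tests on chromosome ends, on chromosome 7 alone and on 3q26.2, and the stretch of chromosome 3, were chosen after the results they concern had been seen. The relation between peak density and background across chromosomes was written before it was computed. It was not in the first plan, and its wording already set chromosome 7 apart. Peaks of fold 30 or more concentrated near chromosome ends: 36 of 66 (54.5%, exact 95% interval 41.8 to 66.9) were within 5 Mb of an end, against 21.9% of peaks with a fold of 20 to 30 and 9.99% of those under 20, where 7.10% of placed length lies. With peaks at most 10 kb apart merged, 32 of 58 were near an end against 453 of 5511 (Fisher's exact test, two-sided p = 1.19e-19, peaks of 1 list). The share near an end also rose with tags, from 7.83% at 5 tags to 40.1% at 20 to 99. At 100 tags or more it was 6.98%. Few tags limit the fold, and fold classes were not compared at equal tags. A concentration by fold was thus not separated from one by tags. Of the 66 peaks of fold 30 or more, 57 (86.4%) were in Giemsa-negative bands, which make up 44.8% of placed length, and 0 were pericentromeric. On chromosome 3, the stretch from 20 to 50 Mb, picked for its few peaks among bins of 10 Mb, held 12 against 72.8 expected (ratio 0.165, exact Poisson 95% interval 0.0852 to 0.288, not corrected for that choice). On chromosome 7, each of the 16 bins of 10 Mb was below expectation.

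Repeated DNA collapsed in the reference would raise the background, and the median background index of the peaks of fold 30 or more near an end was 0.678 times that of all other peaks. That value decides nothing, since the index divides by the fold on which the peaks were chosen, and peaks of fold 30 or more at any location had a median index of 1.91 against 2.80 for the list. The share near an end was 5.46 times higher at fold 30 or more than under 20 (intervals 41.8 to 66.9% against 9.25 to 10.8%). That ratio restates the pattern itself, so it is no separate test of a gathering of peaks of every fold alike. Repeated DNA stays open, GC content was not examined here, and no biological explanation was tested, since the design has no second condition.

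The 7 deep, low-fold peaks of 3q26.2 may come from plasmid DNA, which carries the cDNA of the same gene and would be present in input too. All 7 had folds in the lowest 1% of the list, as plasmid reads would need, but these values had been seen first and positions of exons were not analysed here, so this stays open. Extra genomic copies of the 43.2 kb stretch stay open too. The 7 peaks were short, 176 to 409 bp, with 0 other peaks in the stretch. Copies of the whole stretch would raise tags between the peaks as well, but the list gives no tags outside peaks. The median fold of the other peaks within 1 Mb was 13.8, but copies can raise tags and background alike. Those other peaks had background indices of 2.08 to 6.62, against 479 to 1168 for the 7 and a list median of 2.81. Whatever raised the background of the 7 was thus not seen at the other peaks, in this 1 library. Binding at the locus was not decided either, since the median fold of 2.09 is part of the pattern itself and how the background was set is not known.

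The number of peaks per chromosome may follow copy number of the cell line. Across 22 chromosomes without chromosome 7, peak density fell as the share of 5-tag peaks at the lowest background rose (Spearman's rho = -0.767, permutation p = 0.00011, adjusted 0.00015; Pearson's r = -0.677, permutation p = 0.00064, adjusted 0.00064; 4 relations computed). Without chromosomes 14 and 17, the farthest on that share, r was -0.593; any other source of uneven tag density would give the same relation, so copy number itself was not measured. For chromosome 7, low-tag peaks alone are argued against by a ratio of 0.290 among peaks of 8 tags or more, though with 20 tags or more it was 0.750 and did not pass. Peaks of 20 tags or more could lie only in 7p11.1 and 7q11.21, at or next to the centromere. Random loss of its finished peaks from the list is argued against by the share at the lowest background, 77.4% against 37.5% elsewhere (2.06 times, Fisher's exact test, two-sided p = 5.25e-09). That share does not address a loss of chromosome 7 reads before peaks were called. Such a loss could lower tags and background alike and cannot be told apart from copy number here.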
